A study of Mus musculus with 15 samples.

How the data were processed

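The series holds 15 arrays of mouse heart ventricle RNA, which the labels give as biological replicates. The 4 groups were flox control hearts 2 weeks after tamoxifen (n = 4), knockout hearts 2 weeks after tamoxifen (n = 3), flox control hearts 10 weeks after tamoxifen (n = 4) and knockout hearts 10 weeks after tamoxifen (n = 4). Per the labels' protocols, 500 ng of heart RNA was labelled with Cy5 and hybridised to Agilent mouse arrays of 2 colours against a whole mouse reference RNA labelled with Cy3. The software of the scan, the background correction and the scaling within and between arrays are not given in the sources used here.

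The deposited value table holds 41267 probes on 15 arrays, and its values are taken as log2 ratios of heart over reference, as the authors processed them. The log base and the direction of the ratio are not stated. The direction follows the usual order of the dyes that the labels name and is therefore likely rather than settled. With the opposite sign, every rise below would be a fall and every fall a rise, and numbers of called genes and p-values would stay as they are. Each probe had been centred, since the median over the 15 arrays was 0 for all 41267 probes. The values therefore compare arrays within a probe and carry no expression level. No value was missing, and values ran from -4.96 to 8.40. Array medians ran from -0.0196 to 0.0342 and their standard deviations from 0.384 to 0.484. Signal over background was not used here, so the number of arrays sets the precision.

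Probes were joined to mouse gene symbols by their identifiers. In all, 32664 probes carried 1 symbol, 45 carried several, 8465 mouse probes carried none, and 93 spots were array controls. Each gene was the mean of its probes with 1 symbol, which gave 19532 genes, 8511 of them with more than 1 probe. Over those genes the median correlation between probes of a gene was 0.0415, and it lay under 0.3 for 7066 genes. Where the probes of a named gene lay far apart, their values are given. Acsl1 itself was not analysed here, so its loss was not checked in these data.

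Groups were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on all 15 arrays in 1 fit of 4 group means. The fit left 11 residual degrees of freedom, and moderation added 2.07. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 19532 genes of each contrast, and a gene was called at an adjusted p under 0.05. The contrasts were knockout minus control at 2 weeks and at 10 weeks, the difference between these effects, and 10 minus 2 weeks within controls and within knockouts. Errors of log2 differences are standard errors from limma, and errors of group means are standard deviations.

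Across the genome, 37 gene lists covering metabolism, hypertrophy, stress responses and the cell types of heart tissue were tested with camera, which compares a list with all other genes. The preset correlation between genes was 0.01, and p-values were adjusted over the lists of a contrast. Camera was also run with a correlation estimated from the data for each list, and fry, which tests whether the genes of a list move on balance in 1 direction, was run as an alternative. For each list the members called over all genes are counted beside those called when adjusted over the list alone. The sizes and signs of list shifts are medians over members unless called means.

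The lists, contrasts, thresholds, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text may name, in each contrast of knockout against control, the 10 largest changes in each direction among called genes and up to 4 members of each list with the smallest p. For the differences between times it may name up to 5 genes in each direction, and up to 2 members of each list for the difference between effects. Clone and model names are counted but not named. Ppara was named outside this rule, after its values were seen.

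The tests were tried on simulated data made from 19532 genes with 200 changed genes. A 4-fold change was recovered for 87.5% of changed genes at 2 weeks, 91.0% at 10 weeks and 73.5% for the difference between effects, and a 2-fold change for 54.5% at 2 weeks and 53.5% at 10 weeks. In the same order, false calls were 11 of 186, 12 of 194 and 13 of 160 called genes, then 8 of 117 and 2 of 109. For time in controls with a 4-fold change they were 22 of 205. A list shifted by 0.5 was called in 20 of 20 simulations, and 1 of 691 other lists was called. The simulated genes varied independently of each other, so these simulations could not show false list calls from genes that vary together.

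Alternatives covered scaling of the arrays, the choice of probe, the arrays entered in the fit, moderation, array weights, a fold threshold of 1.5, a block for replicate numbers, tests of single probes and leaving out each array in turn. Control spots and probes with several symbols or none were left out of the gene counts. Correlations across genes were tested by exact permutation of arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the table and drew the figures.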

Results

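Hearts of a mouse line with an inducible knockout of Acsl1, a long-chain acyl-CoA synthetase that activates fatty acids for oxidation, were compared with hearts of flox controls. Male mice of 6 to 8 weeks of age received tamoxifen at 75 mg/kg for 4 days, which per the labels deletes the gene in hearts of the knockout line and leaves it in littermates that carry only the flox alleles. Ventricles were taken 2 or 10 weeks later. No group carried the inducible recombinase without deletion of Acsl1, so effects of the deletion could not be told apart from effects of the recombinase itself. Below, an effect of the knockout covers both. The series title names mTOR, a kinase that drives growth and amino acid metabolism, together with hypertrophy and a switch of cardiac fuel. The arrays comprised 8 controls and 7 knockouts, with 4 controls and 3 knockouts at 2 weeks and 4 of each at 10 weeks. Values are log2 ratios to a common reference, centred on 0 for each probe, so that only differences between arrays are reported.

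The first question was what had changed 2 weeks after deletion. Myh7, the slow myosin heavy chain of the fetal heart, rose by 2.46 ± 0.31 (log2 difference ± SE, 3 knockouts against 4 controls, adjusted p = 0.0393). All 3 knockouts lay above all 4 controls, and its 2 probes gave 2.51 and 2.40. Of the 19532 genes, limma called this 1, against 1417 at an unadjusted p under 0.05. The natriuretic peptides, which a stressed heart secretes, did not pass over all genes. Nppa differed by 1.28 ± 0.30 (adjusted p = 0.366) and Nppb by 1.09 ± 0.34 (adjusted p = 0.526), each with 2 of 3 knockouts above all controls. The highest control for Nppa was flox control 2 weeks replicate 1, at 0.40 against -0.81 to -0.32 on the other 3, and that array also had the highest score for markers of atrium and conduction, 1.11. The log2 difference of Myh7 ran from 2.29 to 2.78 when 1 array was left out, but its call was not stable to the loss of 1 array. Its adjusted p was 0.0558, 0.211 and 0.169 without flox control 2 weeks replicates 1, 2 and 4, then 0.0809 and 0.0505 without flox control 10 weeks replicates 1 and 4. Without knockout 10 weeks replicates 1, 2, 3 and 4 it was 0.0802, 0.0895, 0.0976 and 0.0950. The number of called genes was 0 without flox control 2 weeks replicate 2 or 4, flox control 10 weeks replicate 1 or any 1 of the knockout 10 weeks replicates, 2 without flox control 2 weeks replicate 3, and 10, 8 and 9 without knockout 2 weeks replicates 1, 2 and 3. It was 0 after quantile normalisation, 3 with the most variable probe of each gene, and 1 in a fit of the 2-week arrays alone, where the called gene was another. When the probes of these genes were tested singly, 5 probes were called.

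Genes of the extracellular matrix and of fibroblasts lay higher as groups in knockouts at 2 weeks. Of 37 matrix genes, 33 lay above 0, with a median log2 difference of 0.52, and of 20 fibroblast markers 18 did, with a median of 0.60. Both lists were called by camera, with adjusted p = 1.4e-13 for the matrix and adjusted p = 1.2e-09 for fibroblasts. Neither call held when the correlation was estimated, with adjusted p = 0.312 with an estimated correlation for each. No member was called over all genes, and 9 matrix genes and 7 fibroblast markers were called when adjusted over the list alone, with 2 genes common to the lists. Among them Mmp2, a protease that degrades matrix, differed by 1.11 ± 0.24 (adjusted p = 0.343 over all genes), and Sulf1, which trims heparan sulfate, by 0.82 ± 0.18 (adjusted p = 0.343). The fibroblast marker Dpep1 differed by 0.79 ± 0.19 (adjusted p = 0.371), and the collagen-binding Lum by 1.03 ± 0.27 (adjusted p = 0.441). All 3 knockouts lay above all 4 controls for each of these 4 genes. Averaged over the list, the matrix score was 0.63 ± 0.45 (SD, n = 3) in knockouts and -0.01 ± 0.30 (SD, n = 4) in controls. The highest of the controls was flox control 2 weeks replicate 1, at 0.38 for the matrix and 0.33 for fibroblasts. Other cell markers also parted the 2-week groups. The red blood cell score ran from -0.35 to -0.17 in knockouts and from -0.15 to 0.08 in controls (adjusted p = 0.0834 for the list), and that of nerve and Schwann cells from -0.21 to -0.04 and from 0.04 to 0.30 (adjusted p = 0.539). An exact two-sided permutation of the 2-week arrays gave p = 0.0857 for the mean of either list, where 0.0286 is the smallest p these 35 splits allow.

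The list of genes raised in hypertrophy also lay higher at 2 weeks, with a median of 0.19 over 31 genes (adjusted p = 6.2e-04, and adjusted p = 0.371 with an estimated correlation). Of its members 1 was called over all genes and 2 when adjusted over the list alone, Myh7 and Nppa. Without knockout 2 weeks replicate 3 this list had an adjusted p of 0.101. Genes of oxidative phosphorylation lay lower, with a median of -0.07 over 59 genes (adjusted p = 0.00129, and adjusted p = 0.693 with an estimated correlation). No member of that list was called, over all genes or over the list alone, and its adjusted p was 0.0550 without flox control 2 weeks replicate 4 and 0.225 without knockout 2 weeks replicate 2. Markers of skeletal muscle had a median of -0.17 over 20 genes (adjusted p = 0.0263, and adjusted p = 0.371 with an estimated correlation). That call ended without flox control 2 weeks replicate 1 or 3 (adjusted p = 0.0697 and 0.231) or knockout 2 weeks replicate 2 or 3 (adjusted p = 0.225 and 0.102). In all 5 lists were called, 8 without knockout 2 weeks replicate 1, 3 without replicate 2 or 3 of that group, and 0 with an estimated correlation or with fry. Fatty acid oxidation and PPAR targets (median -0.04, adjusted p = 0.748) and mTORC1 and ATF4 genes (median 0.02, adjusted p = 0.748) were not called at 2 weeks.

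Among the largest rises in knockouts at 10 weeks were those of glutathione transferases that detoxify lipid peroxidation products, Gsta2 by 3.79 ± 0.35 (adjusted p = 3.5e-04) and Gsta1 by 3.58 ± 0.41 (adjusted p = 0.00134). Nmrk2, a kinase on the route from nicotinamide riboside to NAD, rose by 3.72 ± 0.39 (adjusted p = 6.6e-04), and Mthfd2, a mitochondrial enzyme of the folate cycle, by 3.41 ± 0.38 (adjusted p = 9.5e-04). Gpr22, an orphan receptor of heart and brain, fell by 2.91 ± 0.46 on the log2 scale (adjusted p = 0.0114). Smim5 fell by 2.42 ± 0.24 (adjusted p = 4.3e-04) and the tubulin-binding Tppp fell by 2.02 ± 0.28 (adjusted p = 0.00499). For each of these genes all 4 knockouts lay beyond all 4 controls. In all, limma called 134 of 19532 genes, 70 higher and 64 lower, and 105 of them differed at least 1.5-fold; 1945 genes had an unadjusted p under 0.05. Of the 134 genes, 45 (33.6%) were called each time when the 15 arrays were left out in turn.

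The number called at 10 weeks was 70, 73, 88 and 66 without flox control 10 weeks replicates 1, 2, 3 and 4, and 83, 61 and 62 without knockout 10 weeks replicates 1, 2 and 4. It was 89 with the most variable probe of each gene and 50 in a fit of the 10-week arrays alone, 37 of them among the 134. When the probes of these genes were tested singly, 207 probes were called.

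**Figure D1:**
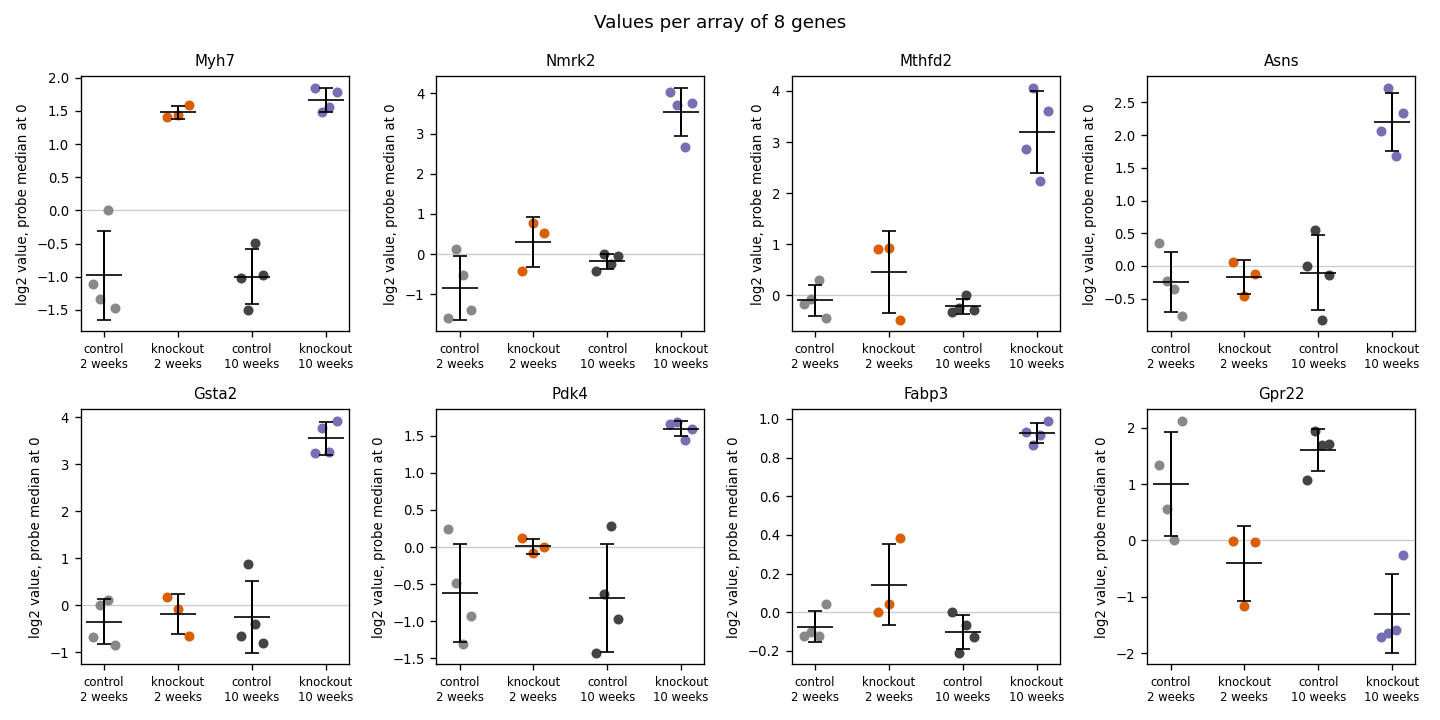
Log2 values of 8 genes, centred on 0 for each probe, with 1 point per array, the 4 groups on the horizontal axis and black bars for the mean ± SD. Myh7 was high in knockouts at both times, while Gsta2 and Asns in the 3 knockouts of 2 weeks lay among the controls of both times and in the 4 knockouts of 10 weeks above them.

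Genes of amino acid and one-carbon metabolism that mTORC1 and the stress factor ATF4 are known to induce rose together at 10 weeks. The 39 measured genes had a median log2 difference of 0.39 (adjusted p = 8.2e-14, and adjusted p = 0.00225 with an estimated correlation), and 32 lay above 0. Over all genes 8 members rose and none fell, and 14 rose when adjusted over the list alone. Besides Mthfd2, these included Asns, the asparagine synthetase, at 2.30 ± 0.30 (adjusted p = 0.00344), the transcription factor Atf5 at 1.25 ± 0.16 (adjusted p = 0.00295) and the hormone Fgf21 at 2.28 ± 0.27 (adjusted p = 0.00134). The probes of Fgf21 differed, at 0.32 and 4.24. Chac1, which degrades glutathione, rose by 1.74 ± 0.29 (adjusted p = 0.0162), but its adjusted p was 0.0542 and 0.05 without flox control 10 weeks replicates 1 and 4, and 0.0583 and 0.0572 without knockout 10 weeks replicates 2 and 4. The mean of the list was 0.53 ± 0.13 (SD, n = 4) in knockouts and -0.09 ± 0.08 (SD, n = 4) in controls.

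The components of the mTOR pathway itself were not called as a group, with a median of -0.06 over 44 genes (adjusted p = 0.438). Of them 1 fell over all genes, and 1 rose and 3 fell when adjusted over the list alone. That 1 was Sesn1, a stress protein that restrains mTORC1, at -1.64 ± 0.31 (adjusted p = 0.0317), with probes at -0.97, -1.40 and -2.55. Its call ended without any 1 of the flox control 10 weeks replicates 1, 2, 3 and 4 (adjusted p = 0.0681, 0.0808, 0.0881 and 0.0806) and without knockout 10 weeks replicates 2, 3 and 4 (adjusted p = 0.0757, 0.0789 and 0.0975).

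Genes of fatty acid oxidation and targets of the PPAR nuclear receptors also rose together at 10 weeks. The 45 measured genes had a median of 0.25 (adjusted p = 1.1e-14, and adjusted p = 0.00933 with an estimated correlation), with 39 above 0. Over all genes 7 rose and 1 fell, and over the list alone 19 rose and 3 fell. Fabp3, the fatty acid binding protein of heart, rose by 1.03 ± 0.10 (adjusted p = 3.5e-04), and the acyl-CoA thioesterases Acot2 and Acot1 rose by 1.89 ± 0.19 (adjusted p = 4.3e-04) and 1.39 ± 0.16 (adjusted p = 0.00107). Pdk4, which holds glucose carbon out of the citrate cycle, rose by 2.28 ± 0.34 (adjusted p = 0.00868). The member that fell was the receptor Ppara, at -0.95 ± 0.16 (adjusted p = 0.0162), and its adjusted p was 0.0571 and 0.0572 without knockout 10 weeks replicates 2 and 4. The list mean was 0.27 ± 0.03 (SD, n = 4) in knockouts and -0.10 ± 0.05 (SD, n = 4) in controls. The score of adipocyte markers moved the same way, from 0.05 to 0.26 in knockouts and from -0.12 to -0.03 in controls, though that list was not called (14 genes, adjusted p = 0.167). Cidea, the 1 gene on both lists, rose by 0.69 ± 0.12 (adjusted p = 0.0249), and its adjusted p lay between 0.0616 and 0.0733 without flox control 10 weeks replicate 1, 2 or 3 or knockout 10 weeks replicate 1, 2 or 4.

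Other lipid genes changed singly. Srebf1, the transcription factor of fatty acid synthesis, rose by 1.22 ± 0.11 (adjusted p = 3.5e-04), and the phospholipid enzyme Agpat3 by 0.50 ± 0.08 (adjusted p = 0.0107), with probes at 0.65 and 0.35. Over the 30 SREBP genes of sterol and fatty acid synthesis the median was 0.08 (adjusted p = 0.0205, and adjusted p = 0.0591 with an estimated correlation), with 3 called over all genes and 4 when adjusted over the list alone. That list was not called with the most variable probes (adjusted p = 0.140), without flox control 10 weeks replicate 3 (adjusted p = 0.0936) or without knockout 10 weeks replicate 1 (adjusted p = 0.0705). Acyl-CoA synthetases, the enzyme family of Acsl1, and thioesterases, which act in the opposite direction, formed 1 list that was not called (29 genes, adjusted p = 0.106). The 2 members that rose were the thioesterases Acot1 and Acot2, and no synthetase was called. Synthesis of triacylglycerol and phospholipids and lipolysis was not called either (41 genes, adjusted p = 0.117), with 2 members higher and 1 lower over all genes and 3 higher and 1 lower over the list alone.

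Antioxidant and glutathione genes rose as a group at 10 weeks, with a median of 0.13 over 47 genes (adjusted p = 3.2e-04, and adjusted p = 0.0430 with an estimated correlation). Over all genes 3 rose and none fell, while 12 rose and 5 fell when adjusted over the list alone. The members that rose over all genes were Gsta2, Gsta1 and Gpx4. Gpx4, which reduces lipid peroxides, rose by 0.46 ± 0.08 (adjusted p = 0.0235), and its adjusted p lay between 0.0598 and 0.0736 without flox control 10 weeks replicate 2, 3 or 4 or knockout 10 weeks replicate 1, 2 or 4. The list mean was 0.27 ± 0.08 (SD, n = 4) in knockouts and -0.03 ± 0.08 (SD, n = 4) in controls. That mean includes Gsta2 and Gsta1, whose rises lay far above the median of 0.13.

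Targets of the hypoxia response fell as a group at 10 weeks, with a median of -0.41 over 20 genes (adjusted p = 0.00154, and adjusted p = 0.0303 with an estimated correlation), and 18 lay below 0. The list mean was -0.17 ± 0.07 (SD, n = 4) in knockouts and 0.21 ± 0.11 (SD, n = 4) in controls, where it had been -0.02 ± 0.04 (SD, n = 4) in controls of 2 weeks. When adjusted over the list alone 4 fell and 1 rose, and over all genes 1 rose and none fell. The member that rose was Hif1a, which encodes the oxygen-regulated transcription factor, at 1.03 ± 0.17 (adjusted p = 0.0147). The glucose transporter Slc2a1 was at -0.43 ± 0.10 (adjusted p = 0.0837) and the mitophagy receptor Bnip3 at -0.60 ± 0.14 (adjusted p = 0.0921), with all 4 knockouts below all 4 controls for both. Ldha, the lactate dehydrogenase of glycolysis, fell by 0.54 ± 0.10 (adjusted p = 0.0278). Without flox control 10 weeks replicates 1, 2 and 4 the adjusted p of Ldha was 0.0829, 0.0754 and 0.0830, and without knockout 10 weeks replicates 1, 2 and 4 it was 0.0726, 0.0724 and 0.0743. Genes of glycolysis and glucose uptake were not called as a group (33 genes, median -0.05, adjusted p = 0.517), with 1 lower over all genes, and 1 higher and 3 lower over the list alone.

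Myh7 was raised at 10 weeks as well, by 2.66 ± 0.28 (adjusted p = 6.6e-04). The list of genes raised in hypertrophy had a median of 0.13 over 31 genes (adjusted p = 1.4e-04, and adjusted p = 0.165 with an estimated correlation). Of its members 2 rose over all genes, Myh7 and Nmrk2, and 6 when adjusted over the list alone. Acta1, the skeletal actin that the fetal heart expresses, was at 1.05 ± 0.23 (adjusted p = 0.0629) and passed without knockout 2 weeks replicate 2 (adjusted p = 0.0351) or 3 (adjusted p = 0.0202). Adult contractile and calcium genes that fall in hypertrophy had a median of -0.18 over 23 genes (adjusted p = 0.0441, and adjusted p = 0.512 with an estimated correlation), with none called over all genes and 1 lower over the list alone. That call ended without flox control 2 weeks replicate 1 (adjusted p = 0.0538), knockout 2 weeks replicate 2 (0.0502), flox control 10 weeks replicate 2 or 4 (0.152 and 0.143) or knockout 10 weeks replicate 1 or 4 (0.344 and 0.0552).

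Fibroblast markers had a median of 0.44 over 20 genes at 10 weeks (adjusted p = 6.7e-05, and adjusted p = 0.270 with an estimated correlation), with none called over all genes and 1 when adjusted over the list alone. Genes of the extracellular matrix had a median of 0.18 over 37 genes (adjusted p = 0.0287, and adjusted p = 0.778 with an estimated correlation), with none called either way. The matrix call ended without flox control 10 weeks replicate 3 or 4 (adjusted p = 0.0711 and 0.0733) and without knockout 10 weeks replicate 1 or 2 (0.294 and 0.0546). Markers of cardiomyocytes (24 genes, median -0.05, adjusted p = 0.969), of endothelium (21 genes, median 0.05, adjusted p = 0.197) and of macrophages (23 genes, median 0.05, adjusted p = 0.255) were not called. The endothelium score nonetheless lay from 0.02 to 0.07 in knockouts and from -0.09 to 0.00682 in controls, and that of lymphocyte markers was 0.12 ± 0.08 (SD, n = 4) and -0.02 ± 0.04 (SD, n = 4), with that list not called (adjusted p = 0.900). In all, 12 lists were called at 10 weeks, 7 without knockout 10 weeks replicate 1, 7 with the most variable probes and 4 with an estimated correlation.

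**Figure D2:**
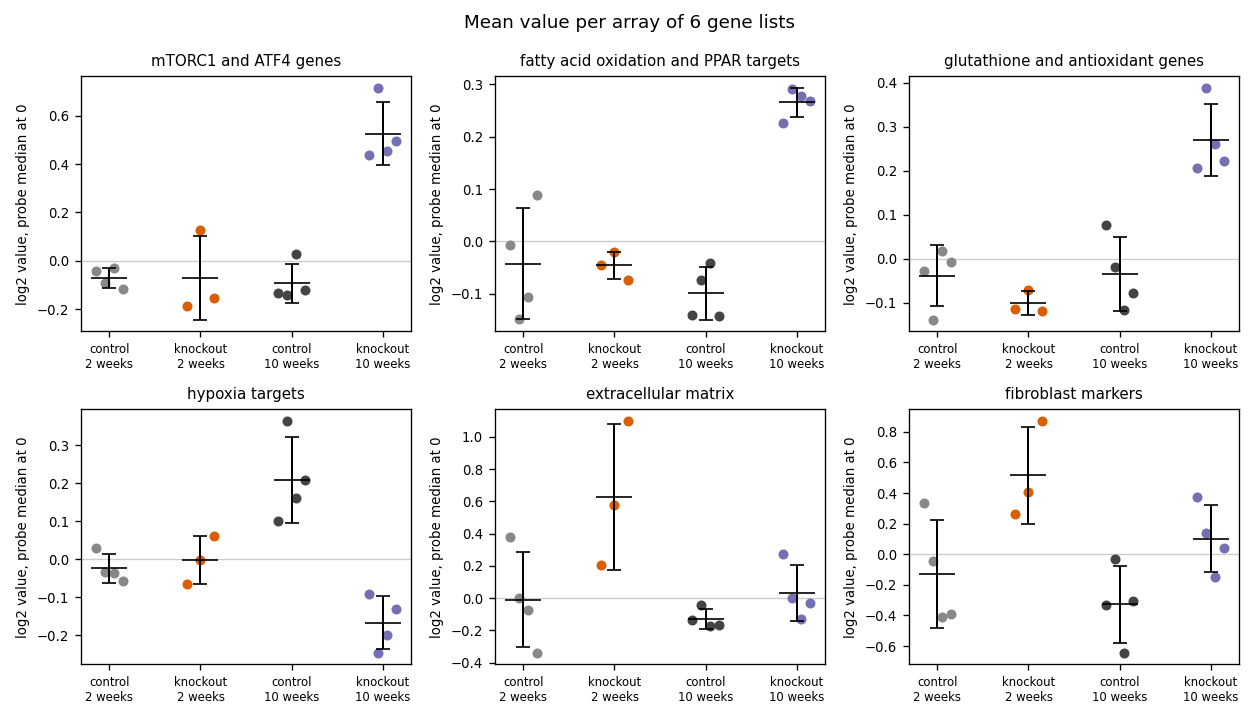
Mean log2 value of 6 gene lists on each array, centred on 0 for each probe, with 1 point per array and black bars for the mean ± SD of the group. The mTORC1 and ATF4 list was at 0.53 ± 0.13 in the 4 knockouts of 10 weeks and at -0.07 ± 0.17 in the 3 knockouts of 2 weeks.

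The next question was whether the effect of the knockout differed between 2 and 10 weeks. No single gene passed this test in limma, against 1331 genes at an unadjusted p under 0.05, and the smallest adjusted p was 0.0901, of Gsta2. Its effect at 10 weeks exceeded that at 2 weeks by 3.63 ± 0.52. Clec4f, a receptor known from liver macrophages, differed by 2.86 ± 0.43 (adjusted p = 0.114), Fgf21 by 2.14 ± 0.39 (adjusted p = 0.166), Fabp3 by 0.81 ± 0.14 (adjusted p = 0.166) and Srebf1 by 0.91 ± 0.17 (adjusted p = 0.166). The number of genes that passed was 4, 1 and 1 without knockout 2 weeks replicates 1, 2 and 3, then 2, 3 and 2 without flox control 10 weeks replicates 1, 2 and 4, and 1 and 2 without knockout 10 weeks replicates 1 and 3. Gsta2 passed without flox control 10 weeks replicate 2 (adjusted p = 0.00557) and Clec4f without knockout 10 weeks replicate 3 (adjusted p = 0.0243). Fgf21 passed when its more variable probe was used, with a difference of 3.81.

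As groups, 4 lists had a more positive difference between knockout and control at 10 than at 2 weeks and kept that call with an estimated correlation. They were fatty acid oxidation and PPAR targets (adjusted p = 2.6e-10, and adjusted p = 0.0339 with an estimated correlation), mTORC1 and ATF4 genes (7.3e-09 and 0.0149), glutathione and antioxidant genes (2.5e-04 and 0.0344) and SREBP genes (0.00909 and 0.0344). For SREBP genes the mean difference was 0.14 at 10 weeks and -0.13 at 2 weeks, where the list was not called (adjusted p = 0.591) although the scores of all 3 knockouts lay below those of all 4 controls (exact two-sided permutation p = 0.0286). The SREBP call ended without flox control 10 weeks replicate 3 (adjusted p = 0.0547). The extracellular matrix (adjusted p = 2.5e-04) and hypoxia targets (adjusted p = 0.0299) had a less positive or more negative difference at 10 weeks, and neither call held, at adjusted p = 0.542 and adjusted p = 0.0891 with an estimated correlation. The matrix call ended without knockout 2 weeks replicate 3 (adjusted p = 0.251). That of hypoxia targets ended without flox control 2 weeks replicate 4 (0.0567), knockout 2 weeks replicate 2 or 3 (0.0857 and 0.0950), flox control 10 weeks replicate 2 (0.0977) or knockout 10 weeks replicate 2 or 3 (0.0529 and 0.0593). No member of these 6 lists was called over all genes.

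Genes changed at 10 weeks tended to lie on the same side at 2 weeks. Of the 134 genes, 112 (83.6%) had the same direction at 2 weeks, more than in any other of the 35 splits of the 2-week arrays, where the highest count was 104 (one-sided exact permutation p = 0.0286, the smallest these splits allow, in a test chosen after the count was seen). Among them 35 also had an unadjusted p under 0.05 at 2 weeks. Gpr22 was at -1.41 at 2 weeks and at -2.91 at 10 weeks, and C4bp-ps1 at 2.64 and 3.09, whereas Asns was at 0.08 and 2.30. The 10-week call of C4bp-ps1 ended in 5 of the 15 fits with 1 array left out (highest adjusted p = 0.0685). Across all 19532 genes, which are not independent replicates, the effects at 2 and 10 weeks had a Pearson correlation of 0.0934 and a Spearman correlation of 0.0705. A one-sided exact permutation of the 10-week arrays gave p = 0.0429 over 70 splits, and the highest other split gave 0.101. That p was 0.0571 and 0.0857 without flox control 2 weeks replicates 1 and 4, 0.0571, 0.0571, 0.0857 and 0.0857 without flox control 10 weeks replicates 1, 2, 3 and 4, and 0.0857 without any 1 of knockout 10 weeks replicates 1, 2 and 4, where r ran from 0.0647 to 0.102. Over the 134 called genes the Pearson correlation was 0.644. These genes were selected by their 10-week effects and that value was not tested over splits, so it is a description only.

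**Figure D3:**
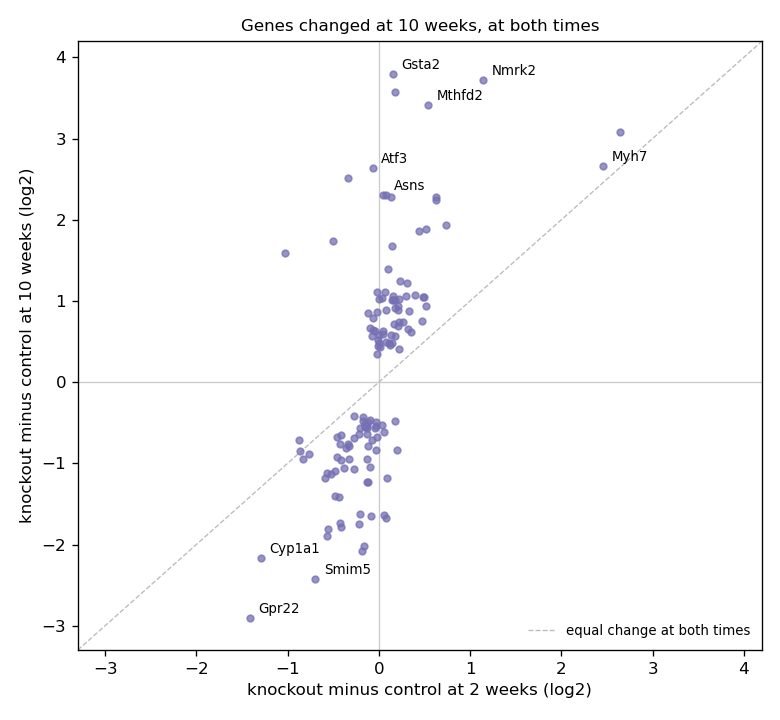
Log2 difference between knockout and control at 2 weeks (horizontal axis) and at 10 weeks (vertical axis) for the 134 genes called at 10 weeks, 1 point per gene, with a dashed line of equal change. Of these genes 112 lay on the same side of 0 at both times, and Myh7 lay near the dashed line at 2.46 and 2.66.

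Time alone was compared within each genotype as background. In flox controls limma called 0 of 19532 genes between 2 and 10 weeks, against 815 at an unadjusted p under 0.05, and 1 without flox control 2 weeks replicate 3 or flox control 10 weeks replicate 4. In knockouts 76 genes were called, 45 higher and 31 lower at 10 weeks, and 25 of them were called each time when the 15 arrays were left out in turn. Gsta2 rose by 3.73 ± 0.38 (adjusted p = 0.00286), Gsta1 by 3.65 ± 0.45 (adjusted p = 0.00429), Nmrk2 by 3.24 ± 0.42 (adjusted p = 0.00564), Chac1 by 2.94 ± 0.31 (adjusted p = 0.00286) and Mthfd2 by 2.75 ± 0.41 (adjusted p = 0.0107). Smim5 fell by 2.30 ± 0.26 (adjusted p = 0.00286). Mxra8 was at -2.31 ± 0.36 (adjusted p = 0.0139), and its adjusted p was 0.0522 and 0.0628 without knockout 2 weeks replicates 1 and 3. The number called was 49 without knockout 2 weeks replicate 2 and 41 without knockout 10 weeks replicate 2, 50 after quantile normalisation and 12 in a fit of the knockout arrays alone, and 155 probes were called when tested singly. Array batch and time since tamoxifen were not separable here, and age rose with time in both genotypes.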

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

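The tests on the control spots, on the share of cardiomyocytes, on the number of knockout arrays and on an effect that differs with time were chosen only after the results were seen; the tests by splits of the arrays, without 1 knockout array, of spread and of genes varying together were chosen before.

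A pair of array control spots, left out of all gene counts, separated the genotypes on every array. AT_nX_3 was at 8.23 ± 0.17 (SD, n = 3) in knockouts at 2 weeks and 7.99 ± 0.31 (SD, n = 4) at 10 weeks, against -0.18 ± 0.04 and -0.12 ± 0.10 in controls, and AT_nX_5 was at 6.68 ± 0.33 and 6.38 ± 0.29, against -0.16 ± 0.14 and -0.21 ± 0.14. A mislabelled genotype would put an array on the other side, and 0 arrays lay there. Control RNA added unequally to the genotypes could move the other AT_n spots as well, and the largest genotype difference among those was 0.383. The centred values carry no level, so whether RNA for those other spots was present is not known. Unequal addition of control RNA was therefore not excluded. A candidate explanation is a transgene that only the knockout line carries, such as the inducible recombinase of the design. The 2 spots differed between 2 and 10 weeks by at most 0.299 in knockouts, as a transgene present at both times would need, but the sequences of the spots were not used here and this stays a hypothesis. It also rests on the direction of the ratio taken here, since with the opposite sign the spots would lie lower in knockouts.

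Matrix and fibroblast lists lay higher in knockouts at 2 weeks, and genes of the list that vary together between arrays of any group stay an open explanation, since 19 of 34 other splits of the 2-week arrays also called the matrix list. With each of the 3 knockouts left out in turn, the highest camera adjusted p was 3.7e-05, for fibroblasts without replicate 3. The matrix list had an adjusted p of 1.4e-18, 2.4e-12 and 2.8e-05 without replicates 1, 2 and 3. A list that most other splits call is likely to stay called, however. Matrix scores were 0.20, 0.58 and 1.10 in knockouts against 0.38 in the highest control. A single array as the source of much of the shift was thus not excluded. A lower share of cardiomyocytes would raise all other cell types alike. The fibroblast score exceeded the mean of 3 other types by 0.55 (exact two-sided permutation p = 0.0571, where 0.0286 is the smallest possible). Those 3 types lay higher in knockouts, endothelium by 0.11, smooth muscle and pericytes by 0.04 and macrophages by 0.13. The cardiomyocyte score differed by -0.04. The red blood cell and nerve scores, picked because they parted the groups, differed by -0.23 and -0.27 (exact two-sided permutation p = 0.0571 for each). The values point both ways and no test reached 0.05, which leaves that explanation and an effect of the knockout open. Whether such an effect came from the deletion or from the recombinase itself could not be told apart here. Over 35 splits of the 2-week arrays, 11 called as many lists as the real 5, with 10 at most in the others, so chance could not be excluded.

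Many more genes were called at 10 weeks (134) than at 2 weeks (1). Fewer knockout arrays at 2 weeks do not account for it, since at least 61 genes were still called at 10 weeks with 3 knockouts, nor does a larger spread, since the median SD within groups at 2 weeks was 1.02 times that at 10 weeks. An effect that differs with time since tamoxifen remains a candidate explanation, since 4 lists differed between the times with an estimated correlation. At 10 weeks 1 of 35 splits, the real one, called as many as 134 genes, and the highest other called 2. That is the smallest share these splits allow, so chance is an unlikely source of the 134 genes but was not strictly excluded. At 2 weeks 18 of 35 splits called at least 1 gene and the highest other called 4, so chance stayed open there.

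Of the other counts, the 12 lists at 10 weeks were reached by 1 of 35 splits, the real one (highest other 9). The 76 genes between times in knockouts were also reached by 1 of 35 (highest other 8). That is the smallest share these splits allow, which makes chance less likely for both without excluding it. As many as the 6 lists that differed between the knockout effects were called in 23 of 100 splits (highest other 11). Those splits moved genotype labels within each time, and so can turn a genotype effect into a difference between times. They therefore neither exclude chance for the 6 lists nor show it. For the 0 genes that differed between the knockout effects (100 of 100, highest other 53) and the 0 genes between times in controls (35 of 35, highest other 1) the splits decide nothing, since every split reaches a count of 0. The split that called 53 genes kept all 4 knockouts of 10 weeks in place and set all 3 knockouts of 2 weeks among the controls, so it added the effects of the 2 times, and the structure it points to is that of genotype.

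Knockout effects differed between the times as a group for 6 lists, of which 4 kept the call with an estimated correlation and 2 did not, hypoxia targets (adjusted p = 0.0891) and the extracellular matrix (adjusted p = 0.542). The mean log2 difference, 10 minus 2 weeks, was 0.62 for mTORC1 and ATF4 genes, 0.37 for fatty acid oxidation and PPAR targets, 0.37 for glutathione and antioxidant genes, 0.27 for SREBP genes, -0.40 for hypoxia targets and -0.48 for the extracellular matrix. The mean of the glutathione and antioxidant genes includes Gsta2 at 3.63 and Gsta1 at 3.40. Among mouse probes without a symbol, 3 were called in knockouts at 2 weeks and 37 at 10 weeks, out of 8 and 246 called probes.

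Single arrays stood far from the other 3 of their group in 12 of the 174 groups tested (6.90%), where chance gives about 1 in 20. In flox controls of 2 weeks, Mgp was at 0.42 on replicate 1, against -0.62 to -0.55 on the others, and Fabp3 was at 0.0445 on replicate 4, against -0.12 to -0.10. In flox controls of 10 weeks, replicate 1 had Atf3 at 0.0574, against -1.71 to -1.44, and replicate 2 had Wfdc3 at 1.47, against -0.28 to -0.05. Replicate 3 of that group had Acta1 at 0.0613, against -0.37 to -0.32, Hif1a at 0, against -0.21 to -0.19, and the mean of the mTORC1 and ATF4 list at 0.0279, against -0.14 to -0.12. On replicate 4 of that group Agpat3 was at -0.0798, against -0.13 to -0.12. In knockouts of 10 weeks, Eif4ebp1 was at -0.50 on replicate 3, against -0.66 to -0.64, and Mxra8 at -0.11, against -1.80 to -1.52. Replicate 4 of the knockouts had Gpr22 at -0.26, against -1.72 to -1.59, and Cep57 at -1.93, against -0.84 to -0.72. Groups of 3 arrays were not tested.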

How the results depend on the processing

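All alternatives were planned before the data were examined except the tests without 3 of the arrays numbered 3. Left out were replicates 3 of flox control 2 weeks, flox control 10 weeks and knockout 10 weeks. They were chosen after seeing that their deviations ran together (r of 0.123, 0.0840 and 0.0532), and knockout 2 weeks replicate 3 was kept. Genes called at 2 weeks (1) numbered 0 after quantile normalisation, 3 with the most variable probe, 0 with a replicate block, 2 without those 3 arrays, and 0 to 10 without 1 array. Those at 10 weeks (134) numbered 89 with the most variable probe, 50 with the 10-week arrays alone, 20 with a replicate block, all among the 134, and 61 to 142 without 1 array. For the difference between effects (0) there was 1 with the most variable probe, and 0 to 4 without 1 array, and for time in controls (0) 0 to 1 without 1 array. For time in knockouts (76) the counts were 50 after quantile normalisation, 12 with the knockout arrays alone, 0 with a replicate block, and 41 to 89 without 1 array. Tested singly, the called probes numbered 5 at 2 weeks, 207 at 10 weeks, 1 for the difference between effects and 155 for time in knockouts. Lists at 2 weeks (5) numbered 0 with an estimated correlation, 0 with fry, and 3 to 8 without 1 array, and lists at 10 weeks (12) numbered 4 with an estimated correlation, 7 with the most variable probe, 7 with a replicate block, and 7 to 12 without 1 array. Lists for the difference (6) ran from 5 to 9 without 1 array. The correlation of effects (0.0934) was 0.0926 without the 3 arrays (one-sided exact permutation p = 0.05) and 0.0647 to 0.109 without 1 array. Direction reversed in 2 cases, 1 probe of Col8a1 at 2 weeks (-0.10) and 1 probe of Tbx5 at 10 weeks (0.43). Over 57 called gene results, 1024 of 1340 alternatives stayed past the threshold in the same direction, 315 fell short and 1 reversed, and Asns, Fabp3, Srebf1, Nmrk2, Myh7, Gsta2, Gsta1 and Smim5 at 10 weeks passed in every alternative run. Correlations of deviations between arrays of the same number ran from -0.034 to 0.123 and were not all over 0.1, so the numbers were not taken as pairs, though the 4 highest of all correlations joined arrays of the same number, a hint from the data and not the design. Fits of fewer arrays and single-probe tests change the degrees of freedom or the features tested; for the other settings the cause was not tested. Not run were those on Acsl1, on the direction of the ratios and on mean level, which need a gene or a level not used here, and complete probes only, since no value was missing. Signal over background was not used here, so weak probes were not set apart.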

Other observations

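The tests of lists between times within each genotype, and the naming of Cd48, Mast4 and Snx12, were chosen only after the results were seen.

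From 2 to 10 weeks in knockouts, genes of fatty acid oxidation and PPAR targets rose (median 0.26, adjusted p = 1.4e-11, and adjusted p = 0.0150 with an estimated correlation), with 3 of 45 called over all genes, and 13 higher and 1 lower when adjusted over the list alone. Genes of mTORC1 and ATF4 rose (median 0.34, adjusted p = 1.8e-10, and adjusted p = 0.00749 with an estimated correlation), with 6 of 39 called over all genes and 16 over the list alone. Glutathione and antioxidant genes rose (median 0.15, adjusted p = 5.0e-07, and adjusted p = 0.0119 with an estimated correlation), with 2 called over all genes, and 12 higher and 1 lower over the list alone. SREBP genes rose as well (median 0.12, adjusted p = 0.00295, and adjusted p = 0.0186 with an estimated correlation), with 1 called over all genes and 4 over the list alone. Extracellular matrix genes were lower at 10 weeks (median -0.52, adjusted p = 3.2e-09, and adjusted p = 0.166 with an estimated correlation), as were fibroblast markers (median -0.32, adjusted p = 0.00375, and 0.457 as adjusted p with an estimated correlation) and smooth muscle and pericyte markers (median -0.27, adjusted p = 0.00760, and 0.166 likewise). Markers of red blood cells were higher (median 0.28, adjusted p = 0.00623, and adjusted p = 0.123 with an estimated correlation), with 3 of 9 called over the list alone. Acyl-CoA synthetases and thioesterases were higher (median 0.09, adjusted p = 0.0365, and adjusted p = 0.123 with an estimated correlation). In flox controls only the hypoxia targets were called between the times, with a median of 0.19 (adjusted p = 0.00735, and adjusted p = 0.0818 with an estimated correlation).

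Immediate early genes, which respond within minutes to growth signals, had a median of 0.30 over 26 genes at 10 weeks (adjusted p = 0.00161, and adjusted p = 0.298 with an estimated correlation), with 2 called over all genes and 3 over the list alone. That list had an adjusted p of 0.0601 without flox control 10 weeks replicate 2. Genes of ribosome biogenesis and translation had a median of 0.18 over 38 genes (adjusted p = 0.0287, and adjusted p = 0.0608 with an estimated correlation), with 1 lower over all genes, and 4 higher and 3 lower over the list alone. That call ended without flox control 10 weeks replicate 3 (adjusted p = 0.0936) and without knockout 10 weeks replicate 1 or 3 (0.0705 and 0.0775). The member that was lower was Eif4ebp1, a brake on translation that mTORC1 releases, at -0.72 ± 0.14 (adjusted p = 0.0400), with probes at -0.11 and -1.32. It was at -0.87 ± 0.16 at 2 weeks (adjusted p = 0.160). At 10 weeks its adjusted p ran from 0.0507 to 0.108 without flox control 2 weeks replicate 2, 3 or 4, knockout 2 weeks replicate 2 or 3, flox control 10 weeks replicate 1, 3 or 4, or any 1 of the knockout 10 weeks replicates.

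Citrate cycle genes had a median of -0.08 over 20 genes at 10 weeks, with none called and 19 below 0 (adjusted p = 0.0477, and adjusted p = 0.663 with an estimated correlation). That call ended without flox control 2 weeks replicate 1 or 3 (adjusted p = 0.0538 and 0.0562), flox control 10 weeks replicate 1 or 4 (0.102 and 0.328) or knockout 10 weeks replicate 1 or 2 (0.250 and 0.150). Lists not called at 10 weeks included oxidative phosphorylation (median -0.02, adjusted p = 0.651), mitochondrial biogenesis (median -0.04, adjusted p = 0.969), autophagy and lysosome (median -0.01, adjusted p = 0.969), the unfolded protein and heat shock response (median -0.11, adjusted p = 0.969), the circadian clock (median -0.15, adjusted p = 0.908), the cell cycle (median -0.00156, adjusted p = 0.990) and the interferon response (median 0.05, adjusted p = 0.939). Markers of adipocytes had a median of 0.16 (adjusted p = 0.167) and markers of skeletal muscle a median of -0.07 (adjusted p = 0.615).

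When 41174 mouse probes were tested singly, 8 were called at 2 weeks and 246 at 10 weeks. At 2 weeks 5 were higher and 3 lower. The 3 lower probes carried no symbol and lay at -3.29 to -3.06, and all 3 were called lower at 10 weeks as well, at -3.52 to -2.67. The 5 higher were both probes of Myh7, 1 probe of Cd48, a receptor of immune cells (2.13 ± 0.22, adjusted p = 0.00267), 1 of Mast4 (1.91 ± 0.25, adjusted p = 0.0192) and 1 of Snx12 (1.07 ± 0.13, adjusted p = 0.0130). Averaged over all probes of the gene, Cd48 differed by 1.22 (adjusted p = 0.160), Mast4 by 0.32 (adjusted p = 0.677) and Snx12 by 0.15 (adjusted p = 0.837).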
